A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

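The samples were 6 poly(A)-selected, directional mRNA sequencing libraries of Saccharomyces cerevisiae SK1, read as 50 bp single ends per the labels' protocols, with 1 library for each of 2 treatments at each of 3 times. Per the submitters' processing notes, Bowtie2, TopHat and SAMtools were used; their versions, the genome build, the annotation and the filters are not given in the sources used here, and neither is whether reads were counted by strand. ORFs that overlap or lie antisense to another gene, and members of near-identical families, are therefore uncertain.

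The authors deposited 1 table of RPKM values for 6679 ORFs, without counts. The unit was read from the values. Within a library, low values were whole multiples of a constant divided by the coding length less 60 bp: 77.7 to 81.0% of values below 40 reads came out whole within 0.02 of a read, against 9.2 to 12.3% without the offset. The values are 2.90 to 2.93 times what reads per kilobase and per megaread of gene reads would give, and the reason for this factor is not given in the sources used here. It is nearly equal in all libraries, so ratios are not affected by it. The recovered read numbers, 6.0 to 21.7 megareads per library, describe depth only; no count test was run. Intervals were not computed from them, and the p-values carry no counting error of their own. HAC1 values came out whole with its coding length of 717 bp in 5 of the 6 libraries.

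Each column was matched to a sample by its name, and 0 columns belonged to unmapped samples. Symbols came from the file and from the reference gene table of the S288C assembly R64; 5994 of the ORF identifiers were in that table and 685 were not, 763 symbols were added from it and 95 updated. Because the authors' build is not named, no coordinates are given, and the reference served for names, coding lengths and for which genes lie next to each other.

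Values were transformed as log2(value + 1), so the change of low genes is understated. ORFs with a mean of at least 5 over the 6 libraries were kept (6025; 654 were left out). The main test was limma-trend (limma 3.58.1 in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. Inducer and vehicle were compared with time as a 3-level factor, which leaves 2 residual degrees of freedom before the prior; change over time used treatment plus hours as a linear term, and the interaction added treatment by hours. The design had been written for counts or for normalised values, and the branch for normalised values was used. The pairing comes from the sampling hour in the labels. Deviations of same-hour libraries from their treatment means correlated across genes at 0.32, 0.00 and 0.11 for 6, 6.5 and 7 h. Mismatched hours gave -0.23 to 0.22, with 0.22 for vehicle at 7 h and inducer at 6.5 h, so the values favour the pairing only at 6 h. Pearson correlations between libraries lay between 0.925 and 0.987, and no library repeated another. The first principal component held 66.9% of the variance and the second 13.9%.

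Before the data were examined, 29 gene lists were fixed with 838 genes, of which 824 were found. The list of small RNAs without a poly(A) tail had no gene in the table, so 28 lists were tested, with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, Benjamini-Hochberg over lists. Counts of members over all genes and adjusted over the list alone are both given. By fry, which tests whether a list's genes move on balance one way, no list passed in either comparison. Its undirected version gave adjusted p under 0.05 for some lists over time, the smallest being 0.00011 for spore wall genes. Camera with an estimated correlation and fry draw on only 2 residual degrees of freedom between inducer and vehicle, or 3 over time. One-way calls over 28 lists were hardly possible with so few, so a list that did not pass is not thereby shown to be unchanged.

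Genes were named by a rule fixed at the same time: HAC1; 16 fixed markers (KAR2, PDI1, ERO1, DER1, INO1, OPI1, RTN1, LNP1, IME1, IME2, ZIP1, NDT80, CLB3, SPS1, DIT1, GCN4); the 10 largest changes in each direction among called genes of one sign at all times with a mean of at least 20; 5 in each direction for the interaction, filled by smallest p where fewer passed; and up to 4 members of each list by smallest p. Any other gene named was chosen after its value was seen.

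The test was tried on simulated data with 6025 genes, 200 of them changed, in 5 runs. It recovered 95.6% of changes of 1 and 98.2% of changes of 2 (log2) between inducer and vehicle with 7% false calls, and 86.4% and 97.6% over time with 5.4% false calls. The noise was drawn independently for each gene from the fitted variances. Genes of the real libraries are correlated, so these shares do not give the false-call rate of the real comparison. The alternatives tried were other pseudocounts, filters and scalings, HAC1 left out of the library totals, each time left out, other codings of time, list tests of other kinds, and, added after seeing the data, reference ORFs only, robust empirical Bayes and list members with a mean of at least 50. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.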

Results

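Poly(A)-selected RNA was sequenced from 6 cultures or culture samples of the budding yeast strain SK1, a laboratory strain that sporulates rapidly, while the cells went through meiosis. Cells had been moved to sporulation medium, and after 5 h either ethanol vehicle or an inducer labelled bEST was added. The series describes the treated cells as having the spliced form of HAC1 expressed strongly from outside its own control. Hac1 is the transcription factor of the yeast unfolded protein response (UPR), and splicing of its mRNA by Ire1 normally permits its synthesis. Each treatment was sampled at 6, 6.5 and 7 h, which is 1, 1.5 and 2 h after the addition, with 1 library per treatment and time. There were thus 3 vehicle and 3 inducer libraries in 3 time-matched pairs, and no replicate of any treatment at any time. The labels give the genotype of all 6 libraries as WT and do not name the construct, and cells given the inducer without a driven HAC1 were not analysed here. The effects of the inducer and of HAC1 therefore cannot be separated.

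The deposited values were RPKM-type values for 6679 open reading frames (ORFs), and 6025 with a mean value of at least 5 were tested. Read numbers recovered from the values were 13.3, 6.0 and 11.7 megareads for vehicle at 6, 6.5 and 7 h, and 9.5, 21.7 and 9.9 megareads for inducer at the same times. The value of 1 read in an ORF of 1 kb ranged from 0.143 in the deepest library, inducer at 6.5 h, to 0.512 in the shallowest, vehicle at 6.5 h. Changes below are on the scale of log2(value + 1), with the standard error (SE) of the fitted coefficient over the 3 pairs, and the adjusted p is from limma with Benjamini-Hochberg correction. Values are means over the 3 libraries of a treatment unless a time is given. The spread behind each SE is the treatment-by-time deviation, and since nothing in the labels says that the libraries came from separate cultures, the p-values measure only the spread between these libraries.

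The first comparison asked whether the libraries carried the driven transcript. HAC1 (YFL031W) stood at 127, 128 and 98.4 in vehicle at 6, 6.5 and 7 h, and at 28926, 48866 and 53257 with inducer. The change was 8.48 ± 0.23 (SE, 3 pairs; adjusted p = 7.84e-06), a 358-fold difference, and HAC1 was the gene with the smallest adjusted p in the comparison. HAC1 took 0.648%, 1.10% and 1.20% of the recovered reads with inducer at the 3 times, against 0.002 to 0.003% in vehicle. IRE1, which encodes the kinase and endonuclease that splices HAC1, changed by -0.17 ± 0.15 (adjusted p = 0.476); it was chosen after its value was seen. A single value per ORF cannot tell spliced from unspliced HAC1.

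The second comparison asked which transcripts differed between cells given the inducer and vehicle at matched times. In the endoplasmic reticulum (ER), 13 of 16 genes for protein folding, 11 of 27 for N-glycosylation and 23 of 37 for traffic between ER and Golgi rose, among them the ER Hsp70 KAR2 (YJL034W), from 942 to 16951. Of 28 early meiotic, 137 ribosomal protein, 35 respiratory and 17 glyoxylate genes 12, 59, 15 and 12 fell, and each of these 7 lists had adjusted p = 0.82 with an estimated correlation. In all, 604 genes were higher and 503 lower with inducer at adjusted p under 0.05. Each of them had the same sign at all 3 times, which a call over 3 pairs largely requires, so the shared sign adds no support. Without the 6 h pair the counts were 723 and 535, without the 6.5 h pair 196 and 22, and without the 7 h pair 76 and 9. The increases were larger: 295 of the higher genes and 76 of the lower genes changed by more than 2-fold, and 78 and 0 by more than 4-fold. The median change was 0.99 for the higher genes, -0.70 for the lower genes and -0.08 for all tested genes.

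The ER chaperone and oxidative folding list had the highest median change of the 28 lists, 2.22, with 13 of 16 members higher and none lower. ERO1, the oxidase that supplies disulfide bonds, rose by 2.96 ± 0.17, SIL1, the nucleotide exchange factor of Kar2, by 3.45 ± 0.23, JEM1, an ER J-protein, by 2.55 ± 0.15, and MPD1, a disulfide isomerase, by 2.40 ± 0.15 (adjusted p between 0.000255 and 0.00038). KAR2 rose by 4.01 ± 0.34 (adjusted p = 0.00082), 16.1-fold, and the disulfide isomerase PDI1 by 1.17 ± 0.21 (adjusted p = 0.0127). The members that did not pass were EPS1, CNE1 and ROT1, at -0.34, -0.17 and -0.16. Among genes of ER-associated degradation, 8 of 17 rose and none fell. DFM1 and DER1, rhomboid-like proteins of the ER membrane, rose by 2.67 ± 0.23 and 2.30 ± 0.24, HRD1, the ubiquitin ligase of the pathway, by 1.27 ± 0.17, and USA1, its scaffold, 3.03-fold (adjusted p = 0.00502). Adjusted over the list alone, 13 chaperone genes were higher and 1 lower, and 9 degradation genes were higher. Both lists ranked above other genes by camera with a preset correlation of 0.01 (adjusted p = 1.1e-10 and 1.9e-05) but not with a correlation estimated from the data (adjusted p = 0.82 with an estimated correlation for both). Without the 6 h pair 13 chaperone and 8 degradation genes were higher, without the 6.5 h pair 10 and 4, and without the 7 h pair 6 and 2. The chaperone median was 2.51, 1.99 and 2.15 in these fits.

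Some genes of protein entry into the ER, of glycosylation and of transport between the ER and the Golgi rose as well. In the translocation and signal peptide cleavage list 11 of 21 members rose and none fell, with SEC62, SEC63, SEC66 and SEC61, all subunits of the translocation complexes, changed by 2.69 ± 0.28, 2.10 ± 0.22, 1.78 ± 0.20 and 1.91 ± 0.24. In the N-glycosylation list 11 of 27 rose and none fell, including the oligosaccharyltransferase subunits OST2 (1.46 ± 0.17) and SWP1 (1.89 ± 0.27) and the mannosyl- and glucosyltransferases ALG12 (1.47 ± 0.19) and ALG6 (1.19 ± 0.16). In the O-mannosylation and glycosylphosphatidylinositol (GPI) anchor list 10 of 26 rose and 1, GPI13, fell. MCD4, an enzyme of GPI anchor synthesis, rose from 56.8 to 1077, by 4.21 ± 0.16 (adjusted p = 3.07e-05), GWT1 by 2.29 ± 0.19, and the O-mannosyltransferases PMT2 and PMT1 by 1.90 ± 0.20 and 1.78 ± 0.24. The median of that list was only 0.07, and 15 of its 26 members did not pass. In the ER-Golgi traffic list 23 of 37 rose and none fell, with a median of 0.80; examples were the cargo adaptors ERP2 (2.43 ± 0.21) and ERV25 (1.74 ± 0.20) and the COPII coat subunits SFB3 (1.70 ± 0.18) and SFB2 (1.56 ± 0.17). Counts adjusted over the list alone were 11, 13, 11 and 27 higher and 0, 0, 1 and 0 lower. The preset camera test gave adjusted p = 8.3e-06, 8.3e-06, 0.0011 and 3e-13, and each list had adjusted p = 0.82 with an estimated correlation. Without the 6 h pair 11, 12, 11 and 25 members were higher. These counts were 4, 5, 7 and 13 without the 6.5 h pair, and 2, 1, 3 and 3 without the 7 h pair.

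Lists for ER shape and for phospholipid synthesis held few calls, and sterol genes went both ways. Of 21 genes of ER shape and contact sites only MDM12, a subunit of the ER-mitochondria encounter structure, rose (0.50 ± 0.12, adjusted p = 0.0342), and none passed adjusted over the list alone. The reticulon RTN1 stood at 0.91 ± 0.27 (adjusted p = 0.0579), with 0.07, 0.98 and 1.67 at 6, 6.5 and 7 h, and the lunapark protein LNP1 at 0.19 ± 0.13. In the phospholipid and inositol list 3 of 21 rose (EPT1, INO2 and OPI3, by 0.65, 0.89 and 1.24) and FAS1 fell by 0.72, while 4 rose and 3 fell adjusted over the list alone. INO1, the inositol synthase often used as a UPR-linked marker, was at -0.19 ± 0.15 (adjusted p = 0.403) and its repressor OPI1 at 0.05 ± 0.18 (adjusted p = 0.867). In the sterol list 3 of 23 rose, among them ERG20 by 1.84 ± 0.21 and ERG27 by 0.99 ± 0.18, and 7 fell, among them ERG5 by 1.23 ± 0.20 and HMG1 by 0.87 ± 0.16. With p adjusted over the list alone 3 sterol genes rose and 9 fell. The preset camera test gave adjusted p = 0.54, 0.80 and 0.079 for these 3 lists. Without the 6 h pair 2, 4 and 4 of their members rose and 1, 1 and 6 fell. Without the 6.5 h pair 0, 1 and 1 rose and 0, 0 and 1 fell, and without the 7 h pair 0, 0 and 1 rose and none fell.

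**Figure D1:**
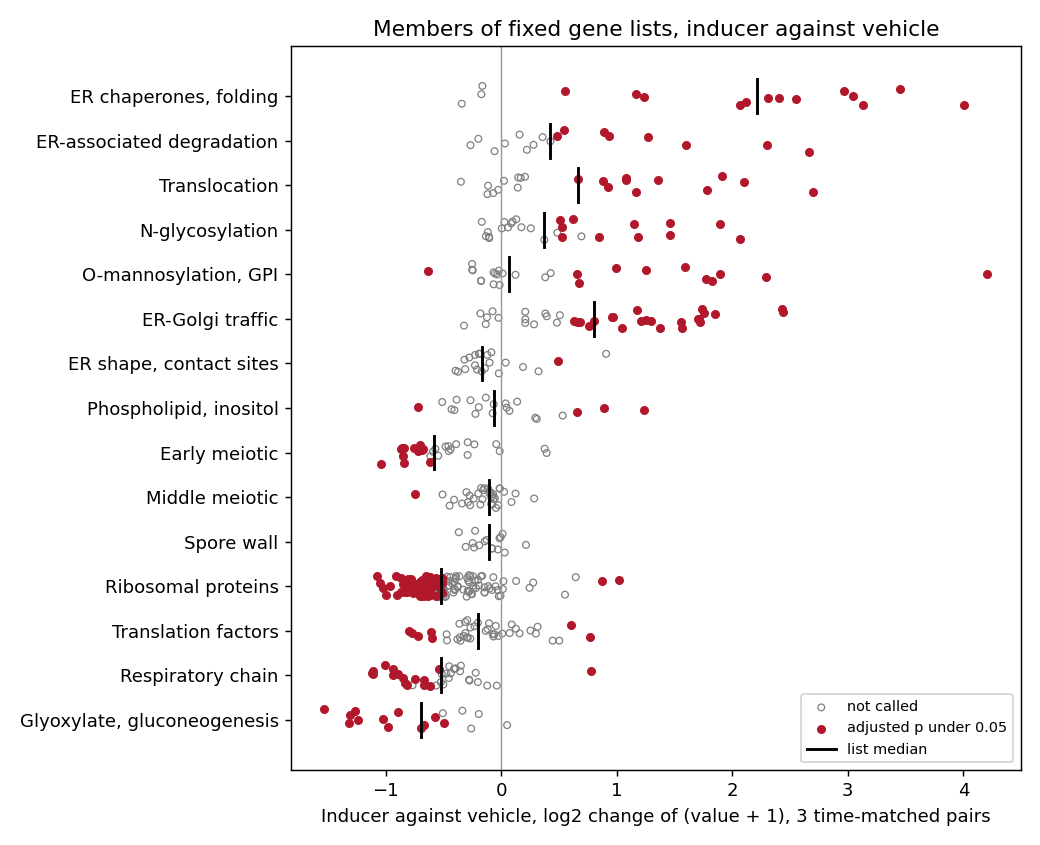
Each point is 1 gene of a list fixed before the data were examined, placed on the horizontal axis at its log2 change between inducer and vehicle over 3 time-matched pairs; filled points have an adjusted p under 0.05, open points do not, vertical bars are list medians, and the vertical jitter carries no value. The ER chaperone median lies at 2.22 and the ER-Golgi traffic median at 0.80, while the glyoxylate, early meiotic, ribosomal protein and respiratory medians lie at -0.69, -0.58, -0.52 and -0.52.

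Some early meiotic genes were lower with inducer, while few middle and late genes passed the test. Of 28 genes of recombination and synapsis 12 fell and none rose, with a median of -0.58. IME1, the master regulator of meiotic entry, fell from 1852 to 957, by 1.04 ± 0.20 (adjusted p = 0.0144), and ZIP2, SPO13 and RED1 fell by 0.84 ± 0.16, 0.85 ± 0.17 and 0.72 ± 0.15. The kinase gene IME2 and the synaptonemal complex gene ZIP1 were at -0.61 ± 0.20 (adjusted p = 0.0769) and -0.48 ± 0.14 (adjusted p = 0.057). In the middle meiotic list 1 of 34 genes fell, SPO1, by 0.75 ± 0.19, and none rose. NDT80, the transcription factor of middle genes, was at -0.27 ± 0.17, the B-type cyclin CLB3 at -0.16 ± 0.15 and the kinase SPS1 at -0.08 ± 0.16. None of 16 spore wall genes passed by limma over all genes or adjusted over the list alone, and DIT1, an enzyme of the dityrosine layer, was at 0.22 ± 0.14 (adjusted p = 0.318). Adjusted over the list alone 18 early genes fell and 1 rose, and no middle gene passed. The medians at 6, 6.5 and 7 h were -0.15, -0.62 and -0.91 for early genes and 0.02, 0 and -0.43 for middle genes. For spore wall genes they were 0.04, 0 and -0.36, so both later lists were lower at 7 h, from 1 library per treatment. The early list had adjusted p = 1.7e-05 by the preset camera test and adjusted p = 0.82 with an estimated correlation. Without the 6 h pair 19 early genes fell and 1 rose, and without the 6.5 h or the 7 h pair none passed. The early median in these fits stayed negative, at -0.78, -0.55 and -0.37. Markers of cells outside meiosis held few calls, in both directions. Of 21 haploid and mating genes BAR1 and MFA1 rose (1.28 and 1.19) and FUS3 fell by 0.70. Of 16 genes of mitotic G1 cells DSE1 and PRY3 rose (3.99-fold and 2.40-fold) and PCL1 fell by 0.59. These counts lie near the shares over all tested genes, 10.0% higher and 8.3% lower. The preset camera test gave adjusted p = 0.54 for the haploid list and 0.88 for the G1 list. The counts adjusted over the list alone were 2 and 1 for the haploid list and 3 and 2 for the G1 list. Without the 6 h pair 4 haploid and 3 G1 genes rose and 2 and 0 fell, and without the 6.5 h or the 7 h pair no member of either passed.

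Of 137 cytosolic ribosomal protein genes 59 were lower with inducer and 2 higher, RPS26B and RPL4B, with a median of -0.52. RPL12B fell by 0.96 ± 0.15, RPL34A by 0.77 ± 0.13 and RPP2A by 0.99 ± 0.17 (adjusted p between 0.00837 and 0.0107). Most of these genes have a near-identical copy, so the value of a single copy is uncertain. Among translation factors 5 of 41 fell, including the elongation factor YEF3 by 0.77 ± 0.17 and the near-identical pair TEF1 and TEF2 by 0.79 ± 0.15 and 0.60 ± 0.13, and 2 rose, SUI1 by 0.77 ± 0.18 and SUP45 by 0.60. In the ribosome biogenesis list, with a median of 0.03, 4 of 61 genes rose and none fell, KRR1 by 0.98 ± 0.22, NOG1 by 0.87 ± 0.21, UTP9 by 0.66 ± 0.17 and IMP3 by 0.53 ± 0.14, though none passed adjusted over the list alone. That share is below the 10.0% of all tested genes that rose. GCN4, the activator of amino acid synthesis genes, fell from 3624 to 1802, by 1.09 ± 0.19 (adjusted p = 0.0118), and in the amino acid synthesis list 12 of 53 measured genes, GCN4 itself included, fell and 3 rose. CPA1 fell by 1.10 ± 0.15 and MET6 by 1.36 ± 0.18, whereas MET17 rose by 1.45 ± 0.18. Of these lists, adjusted over the list alone, 84 ribosomal protein genes fell and 3 rose, 5 translation factors fell and 2 rose, and 12 amino acid genes fell and 3 rose. The ribosomal protein and amino acid lists were lower by the preset camera test (adjusted p = 3e-13 and 0.048), with adjusted p = 0.82 and 0.83 with an estimated correlation, and the other lists were not (0.21 and 0.16). Without the 6 h pair 45 ribosomal protein genes, 5 translation factors and 11 amino acid genes fell, and 4, 4 and 5 rose, with 5 biogenesis genes higher. Without the 6.5 h pair no ribosomal protein gene, no translation factor and no biogenesis gene passed, and 1 amino acid gene rose and 1 fell. Without the 7 h pair 1 ribosomal protein gene passed as lower and 1 amino acid gene as higher. The ribosomal protein median stayed negative, at -0.53, -0.37 and -0.63 without the 6, 6.5 and 7 h pair.

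Some genes of respiration and of growth on acetate were also lower. In the glyoxylate and gluconeogenesis list 12 of 17 genes fell and none rose, with a median of -0.69. The malate dehydrogenase MDH2 fell by 1.24 ± 0.18, the malate synthase MLS1 by 1.31 ± 0.19, the carnitine acetyltransferases YAT1 and CAT2 by 1.31 ± 0.20 and 1.53 ± 0.25, and the peroxisomal citrate synthase CIT2 by 1.27 ± 0.20, from 9961 to 4682. In the nuclear respiratory list 15 of 35 fell, among them cytochrome c (CYC1, by 1.11 ± 0.16), cytochrome c1 (CYT1, by 1.12 ± 0.21) and the complex III subunits QCR2 (-1.01 ± 0.19) and RIP1 (-0.89 ± 0.18), and 1, ATP7, rose by 0.78. None of the 7 measured mitochondrially encoded genes passed, and their medians were 0.78, 1.07 and -0.63 at 6, 6.5 and 7 h. Of 25 genes in the list named for cytosolic heat shock, which also holds some mitochondrial chaperones, 7 fell and none rose. They included SSA1 by 0.95 ± 0.18, STI1 by 0.78 ± 0.18, HSC82 by 0.69 ± 0.16 and HSP82 by 0.67 ± 0.16. In these lists 13 glyoxylate, 24 respiratory and 11 heat shock genes fell adjusted over the list alone, and 0, 1 and 0 rose. The preset camera test gave adjusted p = 3.5e-06, 3.9e-07 and 0.0012 for the 3 nuclear lists, and each had adjusted p = 0.82 with an estimated correlation. Without the 6 h pair 10 glyoxylate, 20 respiratory and 8 heat shock genes fell, and 0, 1 and 1 rose. Without the 6.5 h pair 1 glyoxylate gene and none of the other lists passed as lower, and without the 7 h pair none did. The list medians nevertheless stayed negative. Without the 6.5 h pair they were -0.60, -0.39 and -0.28 for glyoxylate, respiratory and heat shock genes. Without the 7 h pair they were -0.84, -0.46 and -0.39.

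Other lists held scattered calls, none with an adjusted p under 0.05 by camera. Of 28 general stress genes 2 rose and 6 fell, with GPH1, glycogen phosphorylase, lower by 1.18 ± 0.21 and SOL4 higher by 1.64 ± 0.41, and 2 rose and 9 fell adjusted over the list alone. Of 10 histone genes HTB1, HTB2, HHT1 and HTA1 fell, HTB1 by 0.78 ± 0.15, and HHT2 rose by 0.69 ± 0.15, with 6 lower and 1 higher adjusted over the list alone. Of 12 drug efflux genes RTA1 and PDR16 rose by 1.54 ± 0.18 and 1.36 ± 0.17 and RSB1 fell by 0.85 ± 0.16, with 2 higher and 2 lower adjusted over the list alone. Of 34 proteasome genes RPN9 rose and PUP1 fell, with 1 and 0 adjusted over the list alone. Of 27 autophagy genes ATG31 rose and CPS1 fell, with 0 and 1 adjusted over the list alone. None of 12 galactose genes passed by limma over all genes or adjusted over the list alone. Without the 6 h pair 3 general stress, 4 histone, 1 drug efflux, 1 proteasome, 1 autophagy and 1 galactose gene fell. In the same order 1, 1, 2, 2, 1 and 0 rose. Without the 6.5 h pair 1 general stress gene fell and 2 drug efflux genes rose, and without the 7 h pair 1 fell and 1 rose. No histone, proteasome or autophagy gene passed in either of these 2 fits.

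The largest changes lay partly outside these lists. They included genes of thiamine metabolism, although of 15 thiamine genes measured 3 rose and 2 fell, with a median of -0.06. Among the 10 largest increases at a mean value of at least 20 were THI2, the activator of thiamine genes, at 4.74 ± 0.17, from 73.5 to 2015 (adjusted p = 2.38e-05), and THI20, a thiamine synthesis kinase, from 138.7 to 2675.8 (adjusted p = 0.00137). ULI1 rose by 4.40 ± 0.60, IRC4 by 3.73 ± 0.26 and the deoxyglucose phosphatase DOG1, which has a close copy, by 3.71 ± 0.31. YDR320W-B was listed at 0 in the 3 vehicle libraries and at 41.1, 53.9 and 51.3 with inducer, and YLR349W was at 1.96, 0 and 2.21 in vehicle and 28.1, 150 and 185 with inducer; neither ORF is in the reference table used for names. The 10 largest decreases were the cell surface flocculin FLO11 (-1.53 ± 0.30), CAT2, the phosphate transporter PHO89 (-1.49 ± 0.22), YOR302W, the upstream reading frame of CPA1 (-1.46 ± 0.27), the lactate dehydrogenase CYB2 (-1.41 ± 0.19), ISF1 (-1.41 ± 0.26), the mannoprotein FIT2 (-1.36 ± 0.13), MET6, and YBL039C-A and YPR160W-A, at -1.57 ± 0.31 and -1.41 ± 0.37, which the reference table lacks.

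At single times the number of genes over 2-fold higher and lower was 165 and 43 at 6 h, 436 and 315 at 6.5 h, and 525 and 147 at 7 h (222 lower when median centred), each from 1 library per treatment and with no test. The calls depended on the later pairs. Without the 6 h pair 723 genes were higher and 535 lower, without the 6.5 h pair 196 and 22, and without the 7 h pair 76 and 9. Each of these fits has 4 libraries and 1 residual degree of freedom. Fitted without time as a block, 484 genes were higher and 145 lower, a share of 76.9% higher against 54.6%. When the 6 libraries were split in the other 9 ways, camera with the preset correlation called 8 to 13 lists, against 12 for the real split; the other splits still hold treatment and time differences, so they are no reference without change.

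**Figure D2:**
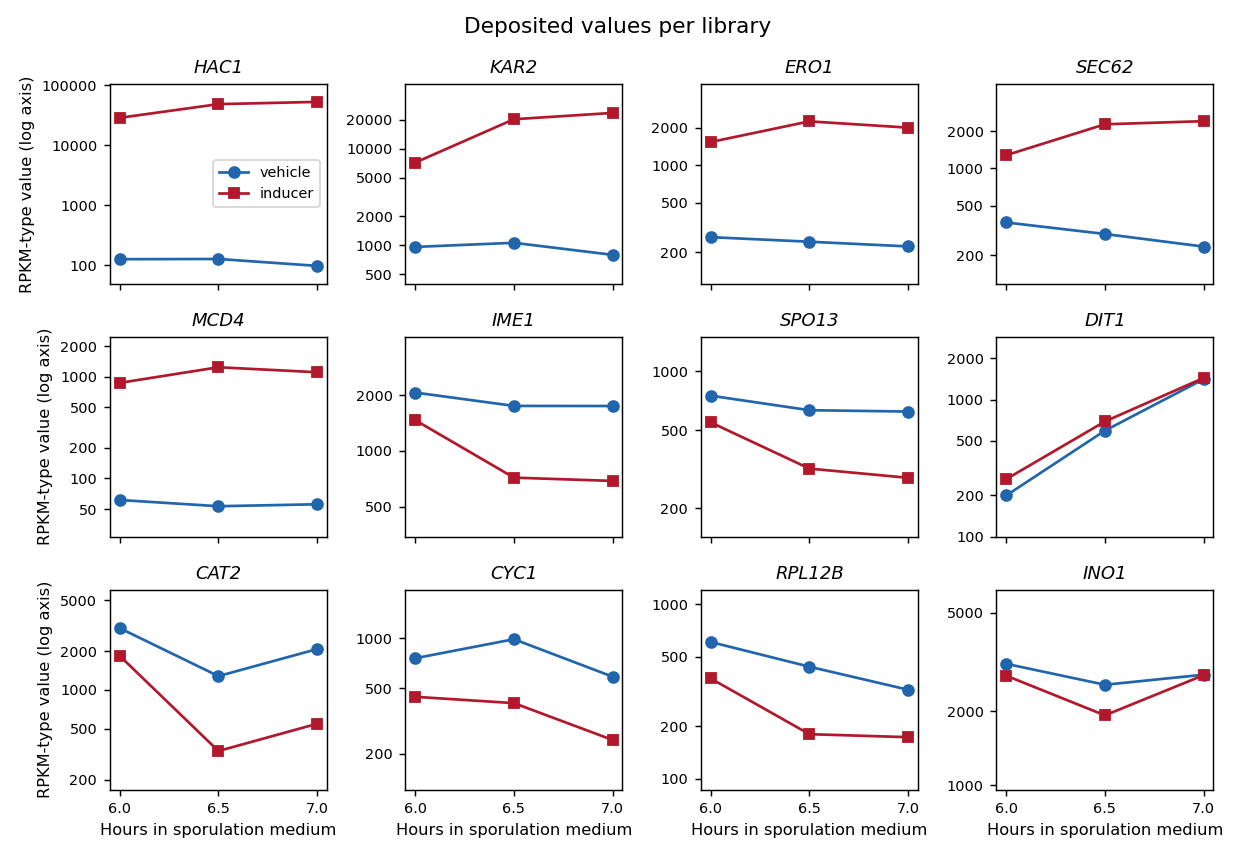
The deposited RPKM-type value of 12 genes is plotted on a log axis against hours in sporulation medium, with 1 library per point, circles for vehicle and squares for inducer. HAC1, KAR2, ERO1, SEC62 and MCD4 are higher with inducer at each time, IME1, SPO13, CAT2, CYC1 and RPL12B are lower, and DIT1 climbs in both arms, from 200 to 1407 in vehicle and from 263 to 1435 with inducer.

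The third comparison asked which transcripts changed between 6 and 7 h in both arms. The dityrosine genes DIT1 and DIT2 rose, and 17 of 137 ribosomal protein genes fell (adjusted p = 0.93 for the list with an estimated correlation). DIT1 and DIT2, the enzymes that make the dityrosine precursor, rose by 2.63 ± 0.17 and 1.20 ± 0.16 per hour (adjusted p = 0.000952 and 0.0299; 7 h above 6 h in both arms). Other increases were YDL218W at 2.87 ± 0.20, the stress gene DDR2 at 2.57 ± 0.23, YLR012C at 2.36 ± 0.22 and GID10, a substrate receptor of the GID ubiquitin ligase, at 1.61 ± 0.14, followed by FMP16, SDD1, ICS2 and FAT3 between 1.22 and 1.58. In all, 15 genes rose and 25 fell, while the median slope of all tested genes was -0.15 per hour; no gene was called without the 6 h or the 7 h pair.

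Of 137 ribosomal protein genes 17 fell and none rose over time, with a median slope of -0.80 per hour, or -0.64 after the libraries were centred on their medians. RPS14B, RPS31, RPP2A, RPL8A, RPL27A and RPL12A fell by 1.16 to 1.38 per hour (adjusted p = 0.0482). The elongation factor YEF3 fell by 1.39 ± 0.24, TIF4631, a scaffold of translation initiation, by 0.89 ± 0.14, GCV1, of glycine cleavage, by 1.32 ± 0.20 and UPS3 by 1.28 ± 0.21. Adjusted over the list alone 122 ribosomal protein genes and 17 translation factors fell, as did 9 of 10 histone, 10 of 34 proteasome, 8 of 23 sterol, 8 of 53 amino acid and 4 of 17 glyoxylate genes. Over all genes no ribosomal protein gene passed when any 1 of the 3 pairs was left out. The general stress list had 2 of 28 genes higher, DDR2 and the glycogen synthase GSY2, and 8 adjusted over the list alone. In the spore wall list DIT1 and DIT2 were higher of 16, with 3 higher and 2 lower adjusted over the list alone; its median slope was -0.14, and 0.02 after median centring. None of the 28 early or 34 middle meiotic genes passed by limma, and NDT80, CLB3, IME1, IME2 and ZIP1 had slopes of -0.25, -0.18, -0.66, -0.84 and -0.50 (adjusted p between 0.134 and 0.546), with SPS1 at 0.45 (adjusted p = 0.18).

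By the preset camera test 2 lists rose over time, general stress (adjusted p = 5.3e-13) and ER chaperones (0.0077; median from 6 to 7 h -0.23 in vehicle and 0.50 with inducer), and 8 fell, led by ribosomal proteins (2.7e-34), translation factors (1.4e-06), proteasome (6e-06) and histones (1.5e-05), then early meiotic, respiratory, ribosome biogenesis and glyoxylate genes. All 10 lists had adjusted p = 0.93 with an estimated correlation. Of the last 4 lists, early meiotic genes had a median from 6 to 7 h of -0.19 in vehicle and -0.86 with inducer. The medians in the same order were -0.21 and -0.72 for respiratory, -0.59 and -0.13 for ribosome biogenesis, and -0.64 and -1.01 for glyoxylate genes. The median slope of all tested genes was -0.15 per hour, so early meiotic and respiratory genes fell mainly in the inducer arm. The counts depended on scaling and on each pair: 42 genes rose and 17 fell after median centring (71.2% higher against 37.5%), 15 and 1 after quantile normalisation, and 9 and 2 with HAC1 left out of the library totals, with 10, 1 and 1 ribosomal protein genes lower. Without the 6 h or the 7 h pair no gene was called, and without the 6.5 h pair 6 rose and 1 fell; the glyoxylate median turned direction to 0.41 without the 6 h pair, and was -2.46 without the 7 h pair, against -0.92 with all.

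The fourth comparison asked whether the inducer's effect grew or shrank with the hours after its addition. No gene passed by limma (smallest adjusted p = 0.0857; 714 genes at an unadjusted p under 0.05). KAR2 stood 2.90, 4.25 and 4.88 above vehicle at 6, 6.5 and 7 h (adjusted p = 0.179), DER1 1.57, 2.55 and 2.79 (adjusted p = 0.226) and HAC1 7.82, 8.56 and 9.07 (adjusted p = 0.235). The smallest p-values on the higher side belonged to YKR012C, YRB2, HUG1, DPH2 and POP1, with differences in slope of 2.44, 2.62, 2.31, 2.27 and 2.76 per hour, and on the lower side to YPL038W-A, YOL038C-A, RNP1, YHL048C-A and ATP20, with -2.01, -2.41, -1.73, -1.62 and -1.35. RTN1 had adjusted p = 0.167. In simulated libraries of this design, with noise drawn independently for each gene, the test recovered 23.6% of differences of 1 and 88% of differences of 2 on the log2 scale.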

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

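List tests on the difference in slope were not among the planned ones and were chosen only after the files had been seen. The slopes over time of 13 gene lists differed between inducer and vehicle by camera with a preset correlation, in the model with treatment by hours. None differed with an estimated correlation (adjusted p between 0.68 and 0.92), and no single gene passed by limma, with 714 at an unadjusted p under 0.05. The difference is given below as the median, over the list's genes, of each gene's slope with inducer minus its slope with vehicle, per hour. It need not equal the difference between the arm medians, and no explanation was weighed for it.

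The differences were above 0 for ER chaperones (0.74), ER-Golgi traffic (0.65), ER-associated degradation (0.47), ribosome biogenesis (0.45), translocation (0.30), ribosomal proteins (0.30) and N-glycosylation (0.29). For ER chaperones the median from 6 to 7 h was -0.23 in vehicle and 0.50 with inducer. For ribosomal proteins it was -0.93 and -0.62, below 0 in both arms.

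The differences were below 0 for mitochondrially encoded genes (-1.36), early meiotic genes (-0.68), middle meiotic genes (-0.49), nuclear respiratory genes (-0.48), spore wall genes (-0.46) and histones (-0.26). For early meiotic genes the median from 6 to 7 h was -0.19 in vehicle and -0.86 with inducer, and for middle meiotic genes 0.07 and -0.40. For the 7 mitochondrially encoded genes, whose transcripts lack the poly(A) tail that the kit selects, it was 0.62 and -0.73.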

How the results depend on the processing

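HAC1 stayed above vehicle and past the threshold under every alternative run, at 8.19 to 8.81. Between inducer and vehicle the counts stayed within 1.5 times of 604 higher and 503 lower except with no replicate block (145 lower) and with a time left out, where 76 to 723 were higher and 9 to 535 lower; such fits have 4 libraries and 1 residual degree of freedom. List calls by camera were 6 higher and 6 lower, and 6 to 7 and 6 to 8 with a time left out. They were 0 and 0 both with an estimated correlation and by fry, which could hardly call any list with so few residual degrees of freedom. Change over time (15 higher, 25 lower) moved most: 8 and 1 with no filter, 24 and 64 with the stricter filter, 42 higher when median centred, 1 lower when quantile normalised, 9 and 2 with HAC1 left out of the totals, 6 and 1 for 7 h against 6 h as factor levels, 23 and 54 with reference ORFs only (added after seeing the data), and 0 to 6 higher and 0 to 1 lower with a time left out. Its lists, 2 higher and 8 lower, became 0 and 0 with an estimated correlation and by fry, and 2 to 5 and 5 to 10 with a time left out. The direction of 6 lists turned in change over time. Their adjusted p without replicate 1 (6 h), without replicate 2 (6.5 h) and without replicate 3 (7 h) was 0.028, 0.00039 and 1.4e-08 for Ribosome biogenesis, 6.3e-05, 0.073 and 8.4e-08 for Cytosolic heat shock genes, and 8.9e-09, 8.7e-06 and 2.9e-11 for Glyoxylate cycle and gluconeogenesis, each turned at the first; and 0.00082, 0.99 and 0.049 for Phospholipid and inositol synthesis, 4.5e-21, 0.00048 and 0.083 for Respiratory chain and ATP synthase (nuclear), and 0.0026, 0.47 and 0.048 for Mitochondrially encoded genes, each turned at the last. At 7 h, 222 genes were over 2-fold lower when median centred, against 147. The interaction called 0 genes under all its alternatives; with any pair left out it has no residual degree of freedom, so no leave-out was run as a test. The cause of these moves was not tested. Among named genes 291 results under an alternative lost the threshold, 195 of them with a time left out, 36 gained it and none reversed. Alternatives planned for counts (other size factors, DESeq2, voom) do not apply to RPKM values and were not run. The shallowest library, vehicle at 6.5 h with 6.0 megareads, limits low genes most.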

Other observations

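All tests here were chosen only after the gene calls had been seen; those on gene neighbours were written down before their own outcome was known, the others after. Some genes of 4 further groups differed with inducer as well. These groups were written down after the values were seen, so that the tests are not independent evidence. HXK1, GLK1 and CRR1 of these groups are also members of fixed lists. Of 19 genes of glycolysis and fermentation 8 rose and 1 fell (Fisher's exact test for an excess of higher genes over 10.0% of all tested genes, adjusted p = 0.0011 over 8 tests). The enolase ENO2 rose by 2.25 ± 0.28, triose phosphate isomerase TPI1 by 1.96 ± 0.24, TDH2 by 1.94 ± 0.27, PGK1 by 1.87 ± 0.29, GPM1 by 1.51 ± 0.25 and pyruvate kinase CDC19 by 1.51 ± 0.27, while TDH3, PDC1 and ADH1 stood at 0.02, 0.27 and 0.18. ENO2, TDH2 and TDH3 have near-identical copies, so their single values are uncertain. TYE7, an activator of glycolytic genes, rose by 2.39 ± 0.14 (adjusted p = 0.000255). Of the 19 genes 9 rose without the 6 h pair, 4 without the 6.5 h pair and 1 without the 7 h pair.

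More cell wall genes fell than rose. Of 34 such genes 21 fell and 1, the protease gene YPS1, rose (adjusted p = 4e-14 for the excess of lower genes over 8.3%), with PST1, HSP150, SED1 and CCW12 lower by 1.34, 1.22, 1.15 and 1.09. Of the 34 genes 22 fell without the 6 h pair, 3 without the 6.5 h pair and none without the 7 h pair. Of 20 iron uptake genes 4 fell, FIT2, FIT3, SIT1 and FET3, and of 15 thiamine genes 3 rose, THI2, THI20 and THI5, and 2 fell, PHO3 and THI7, with adjusted p = 0.21 for the first and 0.37 for the second. THI5 has near-identical copies, so its value is uncertain. With the 6.5 h or the 7 h pair left out 1 iron gene fell, and 3 thiamine genes rose and none fell. Without the 6 h pair 4 iron genes fell and 1 rose, and 5 thiamine genes rose and 2 fell. Among all families of 5 or more genes that share a 3-letter name, RPL and RPS were enriched among lower genes and SEC among higher genes (adjusted p = 5.4e-14, 6.3e-10 and 2.1e-07 over 470 tests), and no other family passed. This test takes genes as independent, and the ribosomal protein list had adjusted p = 0.82 with an estimated correlation. Lower RPL, lower RPS and higher SEC genes numbered 25, 19 and 18 without the 6 h pair, 0, 0 and 8 without the 6.5 h pair and 0, 1 and 2 without the 7 h pair.

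Several genes with no known part in ER function rose next to a strongly induced gene. Strongly induced genes were here the 68 protein-coding genes of the reference annotation that rose by at least 2 on the log2 scale. Of 25 genes transcribed divergently from one of them, 9 rose (36.0%). Of 35 convergent neighbours 3 rose (8.6%), as did 8.9% of all other tested genes of the reference. The excess of divergent over convergent neighbours was 27.4 percentage points (one-sided permutation test, p = 0.0002, 10000 resamples of gene positions). Examples are DDE1 beside DOG1 (1.19), COQ1 beside RER2 (0.91), the cohesin gene SMC3 beside JEM1 (0.89) and NOG1 beside SEC62 (0.87). Transcription or reads running on into the next gene of the same strand was not borne out as a general pattern. Downstream neighbours rose no more often than upstream ones (-1.8 percentage points, 3 of 28 against 4 of 32). With so few neighbours the test cannot exclude run-on at single genes. CTR2, for example, rose by 1.88 downstream of ENO2, which rose by 2.25. A shared promoter may account for some of the genes outside the ER lists, as a hypothesis for the 9 divergent genes, and binding of Hac1 was not measured.

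The fall of ribosomal protein, respiratory and glyoxylate genes was set against a pair of explanations, dilution by the reads of the induced genes and inducer libraries further along in meiosis. The called higher genes took 5.16, 5.09 and 4.70% of reads in vehicle and 9.98, 16.7 and 17.9% with inducer at 6, 6.5 and 7 h. The summed read share of all other genes thus fell by 0.16 on the log2 scale on average (-0.16), taken here as the dilution. That sum includes the genes of the 3 lists themselves. The median change of all tested genes was -0.06, -0.11 and -0.04 at the 3 times, a smaller fall than the dilution at each time. The 189 genes of the 3 lists had a median of -0.53, which is -0.37 beyond that dilution. The bootstrap SE of 0.02 takes genes as independent, although the ribosomal protein list had an estimated correlation of 0.7. It does not measure the spread between the 3 pairs, so the average excess is given without a verdict. At 6 and 6.5 h the dilution was -0.075 and -0.188. The medians there were lower for ribosomal protein (-0.52 and -0.78), respiratory (-0.25 and -0.81) and glyoxylate genes (-0.50 and -1.18), so dilution alone falls short of them. Each of these values is from 1 library per treatment. At 7 h, however, ribosomal proteins had a median of -0.22 against a dilution of -0.215, so dilution is not excluded for them at that time, although the median of all tested genes was -0.04. The respiratory and glyoxylate medians at 7 h were -0.69 and -0.73. If the inducer libraries were further along in meiosis, the ribosomal protein change of -0.52 would need 0.66 h at their slope of -0.80 per hour, and the 15 genes that rose over time would then be higher by 0.95. Their median was 0.16 (SE 0.07), below that value. The 15 genes and their slopes were picked from these same libraries, so 0.95 may be too high. No gene was called over time without the 6 h or the 7 h pair. The gap therefore cannot decide whether the inducer libraries were further along. A response of these genes to HAC1 or to the inducer itself stays open as an untested biological explanation; the design cannot separate them.

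Other splits of the 6 libraries into 3 and 3 cannot give a share under 0.05, since there are 10. The real split called 1107 genes and the highest of the others 0, so 1 of the 10 splits gave as many. Of the other splits, 3 also parted all 3 time pairs, and these called 0 genes as well. For lists called by camera with a preset correlation, 9 of the 10 splits gave as many as the real 12, with 13 as the highest of the others. In every other split some libraries change sides, so its contrast still holds treatment or time differences and its residual holds part of the treatment difference. The other splits are therefore no reference without change, and neither the gene counts nor the list counts can be judged by them.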
